A study of Mus musculus with 6 samples.

How the data were processed

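The deposited files hold 1 row per deduplicated VDJ-seq sequence, a file per library, for 6 libraries of splenic B cell DNA. Per the labels' protocols, B cells were enriched by magnetic depletion of other cells and DNA was extracted with a column kit. The submitters' processing notes name Trim Galore 0.4.4, Bowtie2 2.3.2 and the mm10 build (GRCm38); their parameters, and the version of the tool that called V, D and J genes, are not given in the sources used here. Per the file headers, each row has V, D and J calls, a CDR3, a productive and a frame flag, and a clonotype. Germline V and J identity are a fraction from 0 to 1 per the file headers, and alignment scores are a score per sequence that the authors deposited and that entered no result. The other deposited columns used are lengths in bases. Sequence names carry a J primer tag, which of 2 anchor sequences was read, a 12-base molecular identifier and a trailing number that is taken here as the reads grouped per sequence, an inference from the values (3 or more in every sequence). Row numbers in the files have gaps: the rows present are 56.7% to 64.1% of the highest row number, and the filter behind this is not given in the sources used here.

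From these files, sequences were counted by the first V gene of a call with alleles merged. Calls naming several V genes were 10.3% to 12.1% of sequences, so counts of near-identical genes are uncertain. D families came from the first D call, and 5.28% to 5.68% of sequences had none. CDR3 length was taken from the CDR3 column, since the deposited junction of productive sequences averaged 20.3 to 20.5 bases, against 37.8 to 38.0 for the CDR3. Mismatches were read from the deposited alignment trace, with gaps left out. Coordinates came from the RefSeq annotation of GRCm38.p6, in which 135 of 176 V gene names were found.

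Shares carry Wilson 95% intervals. A V gene stood apart when its ratio of shares was at least 1.5-fold either way and the 95% interval of the log ratio (Katz) excluded 1, among genes with at least 100 sequences over both libraries. Differences of shares and of means, and ratios of numbers on the log scale, carry 95% intervals from the normal approximation, which cover counting error only. No p-value was computed, since each group has 1 library. Depth ranged from 8704 to 112320 sequences, so that a count of 0 allows a share of up to 0.0345% at 500 ng and 0.00267% at 5 µg (3 counts of the total). Diversity was compared after thinning to 8704 sequences over 100 draws. The ratio rule was tested on simulated counts with the real totals: without any change, 5.62 genes had an interval excluding 1 on average in the input comparison (104 genes) and 4.15 in the polymerase comparison (82 genes), and 1.72 and 0.56 stood apart. With 40 genes changed 2-fold, 95.0% and 95.2% of intervals held the true ratio.

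Comparisons, thresholds, gene lists and most alternatives were fixed before the data were examined. The genes named in each comparison are the 10 with the highest mean share, up to 10 with the largest log2 ratio among those whose interval excluded 1, every J gene and D family, and Ighv11-2 and Ighv12-3. Alternatives were other clone definitions, productive sequences only, calls naming a single V gene, other minimum counts and thresholds, thinning and other input pairs. Alternatives chosen after seeing the data were 1 count per clone of V gene, J gene and CDR3, the removal of unclear primer tags, and for mismatches the class of 1 or 2, standardising to read support in bins taken from both libraries pooled, V alignments of at least 150 bases with a single-gene call, and leaving out each library in turn where productive and out-of-frame shares were compared. The V genes of clones found in several libraries, their bases between aligned segments, and the base changes behind mismatches were described after their values were seen. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.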

Results

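Rearranged immunoglobulin heavy-chain (Igh) genes were sequenced from the genomic DNA of splenic B cells of C57BL/6 mice aged 12 weeks by VDJ-seq, which reads the joins of V, D and J genes at the DNA level. There were 6 libraries and each was the only library of its group. A series of 4 libraries was made from 500 ng, 1 µg, 2.5 µg and 5 µg of DNA. A pair of libraries differed by DNA polymerases and carries the names Q5_vent and Q5_Q5; their DNA amount is not given in the sources used here. After removal of duplicates the files held 8704 sequences at 500 ng, 17055 at 1 µg, 56006 at 2.5 µg, 112320 at 5 µg, 19490 for Q5_vent and 15034 for Q5_Q5. With 1 library per group no difference between groups has a replicate check, and every interval below is a 95% interval that covers counting error only.

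The first comparison asked what is recovered across a range of starting DNA. The 5 µg library held 12.9 times as many sequences as the 500 ng library (interval 12.6 to 13.2). Recovery per microgram was 17408 sequences at 500 ng, 17055 at 1 µg, 22402 at 2.5 µg and 22464 at 5 µg. Mean reads per sequence, inferred from the sequence names, were 13.6, 12.6, 7.82 and 10.3 in that order. Rows present were 56.7%, 58.5%, 64.1% and 61.3% of the highest row number. Read support and the unknown row filter thus varied along the series and cannot be told apart from input. The deposited clonotypes numbered 6154, 10683, 27386 and 47779 in the same order, a ratio of 7.76 between 5 µg and 500 ng (interval 7.56 to 7.97). When a clone was instead defined by the same V gene, J gene and CDR3 bases, the CDR3 being the junction of V, D and J that contacts antigen, the numbers were 8615, 16844, 55192 and 110143 and the ratio was 12.8. Deposited clonotypes made up 70.7% of the sequence number at 500 ng and 42.5% at 5 µg, against 99.0% and 98.1% for clones defined by V gene, J gene and CDR3.

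**Figure D1:**
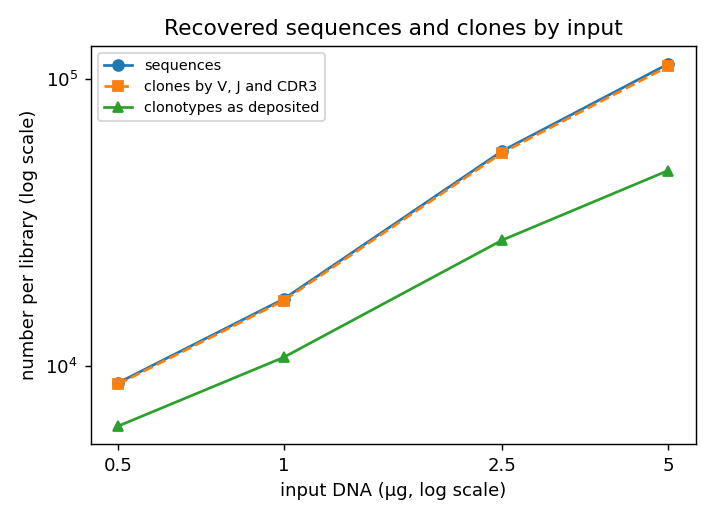
Number of sequences, of clones defined by V gene, J gene and CDR3, and of deposited clonotypes (vertical axis, log scale) against input DNA in µg (horizontal axis, log scale), 1 library per point and no error bars. Sequences went from 8704 to 112320 while deposited clonotypes went from 6154 to 47779.

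The second comparison asked whether the combination of polymerases affects recovery. Q5_Q5 held 0.771 times as many sequences as Q5_vent (interval 0.755 to 0.788). Deposited clonotypes numbered 9540 in Q5_Q5 and 11937 in Q5_vent, a ratio of 0.799 (interval 0.778 to 0.821). Each sequence name carries a number, taken here as the reads grouped into that sequence, and its mean was 12.8 in Q5_Q5 and 8.32 in Q5_vent.

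For V gene usage, the intervals of the 10 most used genes all included a ratio of 1 between 5 µg and 500 ng. Ighv1-26 (chromosome 12, 114788372 to 114788665 in GRCm38) was the most used gene, at 5.16% of sequences at 5 µg and 5.18% at 500 ng, a ratio of 0.995 (interval 0.907 to 1.09). Ighv3-6 (114288152 to 114288447) followed with 3.18% and 2.86%, a ratio of 1.11 (interval 0.978 to 1.26), and Ighv1-64 (115507587 to 115507977) with 2.89% and 2.90%. The other most used genes were Ighv1-18, Ighv1-50, Ighv8-8, Ighv1-72, Ighv1-82, Ighv1-53 and Ighv1-81, and together these 10 genes made up 27.7% of sequences on average over the 4 input libraries. Among genes with at least 100 sequences over both libraries, 103 had an interval including 1 and 4 had an interval excluding it, all lower at 5 µg. Counting error alone leaves 5.35 genes outside on average. These were Ighv3-5 (114262652 to 114262950; 0.172% against 0.276%, ratio 0.623, interval 0.408 to 0.952), Ighv3-2, annotated as a pseudogene (ratio 0.684), Ighv2-9 (ratio 0.742) and Ighv1-4 (ratio 0.790). Of these 4, Ighv3-5 alone passed the 1.5-fold rule, on 24 sequences at 500 ng, where simulated unchanged counts gave 1.72 such genes on average, and 0 passed with the interval widened for the number of genes. Ighv3-2 had a log2 ratio of -0.55 against 500 ng and 0.12 when 5 µg was set against 1 µg, and Ighv1-4 had -0.34 over all calls and 0.02 over calls naming a single V gene.

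Among V families, Ighv1, the most used, made up 56.2% of sequences at 5 µg and 56.8% at 500 ng (ratio 0.989, interval 0.970 to 1.01). Ighv5 made up 8.74% and 8.26%, Ighv3 5.82% and 5.69%, Ighv8 5.63% and 5.35%, and Ighv2 5.48% and 5.77%. The distal families Ighv1 and Ighv8 held 61.8% and 62.2%, and the D-proximal families Ighv2 and Ighv5 held 14.2% and 14.0%. The families between them ranged from 23.6% to 24.4% over all 6 libraries. All these intervals of the ratio between 5 µg and 500 ng included 1 over sequences, while with 1 count per deposited clonotype the middle families differed by 2.35 points (interval 1.18 to 3.51) and the distal families by -1.61 points (interval -2.91 to -0.301). The clonotypes were counted without thinning to equal depth, so input and depth cannot be told apart in these values. Ighv11-2 and Ighv12-3, the genes of phosphatidylcholine-binding B-1 cells, ranged over all 6 libraries from 0.382% to 0.487% and from 0.659% to 0.891%. Among productive sequences Ighv11-2 had a log2 ratio of -0.91 for Q5_Q5 over Q5_vent (interval -1.78 to -0.05), against 0.15 over all sequences. For 5 µg over 500 ng Ighv12-3 had a log2 ratio of -0.00443 over all sequences, 0.46 (interval 0.05 to 0.86) with 1 count per deposited clonotype and -0.40 (interval including 0) among productive sequences.

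Between the polymerase libraries too, the most used genes had intervals including 1. Ighv1-26 made up 5.26% of Q5_Q5 and 4.81% of Q5_vent (ratio 1.09, interval 0.998 to 1.20), Ighv3-6 2.95% and 3.08% (ratio 0.959, interval 0.850 to 1.08), and Ighv1-64 2.93% and 2.76% (ratio 1.06, interval 0.936 to 1.20). Of the 10 most used genes of this pair, 9 were also among those of the input series, with Ighv1-9 in place of Ighv1-81. Of 84 genes compared, 3 had an interval excluding 1, all lower in Q5_Q5, where 4.2 are left outside by counting error alone, and 0 passed the 1.5-fold rule. They were Ighv1-47 (0.479% against 0.657%, ratio 0.729, interval 0.547 to 0.973), Ighv1-62-2 (ratio 0.786) and Ighv1-55 (ratio 0.848). Of 15 families, Ighv7 alone had an interval excluding 1, at 1.43% of Q5_Q5 and 1.72% of Q5_vent (ratio 0.832, interval 0.702 to 0.986). Counting error alone leaves 5% of such intervals outside on average, so 1 family of 15 is not set apart from counting error. In simulated counts with 40 genes changed 2-fold, the rule was scored on those that still reached 100 sequences over both libraries. It found 93.1% of these for the input comparison and 96.8% for the polymerase comparison. Smaller changes, such as 1.5-fold, were not simulated.

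**Figure D2:**
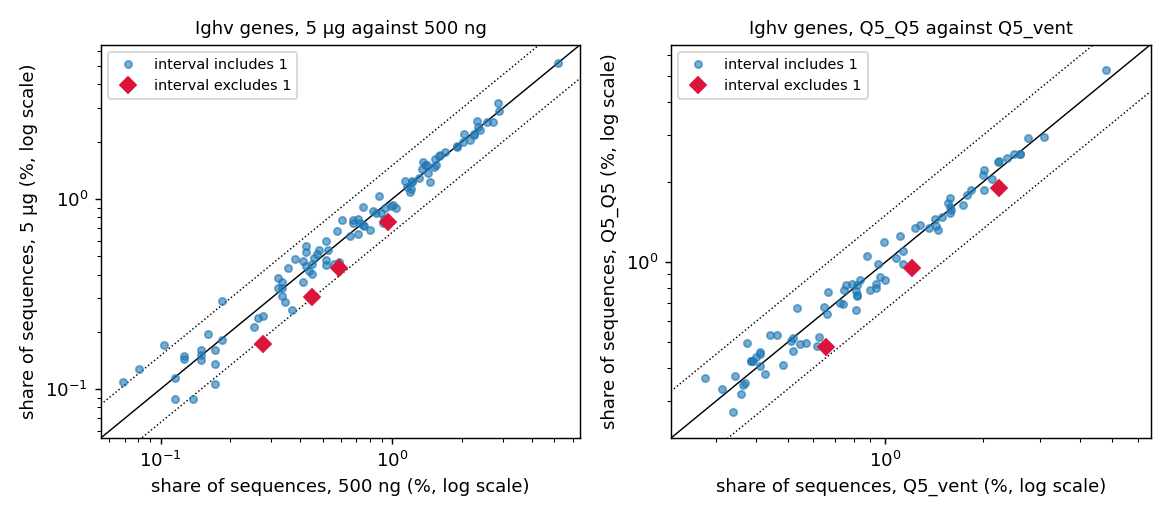
Share of sequences per Ighv gene in percent (log scales), 5 µg against 500 ng on the left and Q5_Q5 against Q5_vent on the right, a point per gene with at least 100 sequences over both libraries. The solid line marks equal shares, the dotted lines a 1.5-fold difference, and diamonds the 4 and 3 genes whose 95% interval of the ratio excludes 1.

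Across all 15 pairs of libraries, Pearson's r of gene shares lay between 0.993 and 0.998 and Spearman's rho between 0.979 and 0.993. These are correlations across genes, which are not independent replicates. Chi-square over degrees of freedom of the gene counts lay between 0.875 and 1.28, where counting error alone gives values near 1. The 5 pairs with the 2.5 µg library had the highest values, 1.12 to 1.28, and the other 10 pairs at most 1.08. Between 2.5 µg and 500 ng, 10 V genes had an interval excluding 1, where counting error alone leaves 5% of compared genes outside on average. The 2.5 µg library also had the longest V alignments (median 179 bases, against 171 at 500 ng). Its share of calls naming several V genes was the lowest (10.3%, against 11.9% at 500 ng). Input and these differences in V calling cannot be told apart.

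Among J genes, Ighj2 was lower and Ighj3 higher at 5 µg than at 500 ng. Ighj2 (chromosome 12, 113429468 to 113429515) made up 28.3% of sequences at 5 µg and 30.9% at 500 ng, a difference of -2.57 percentage points (interval -3.57 to -1.56). Ighj3 made up 25.5% and 23.3%, a difference of 2.20 points (interval 1.27 to 3.12). The intervals for Ighj1 (19.1% and 18.3%) and Ighj4 (27.1% and 27.5%) included 0. Sequences whose primer tag is marked unclear were 11.7% at 5 µg and 12.2% at 500 ng. Of these, 62.6% and 69.0% were called Ighj2, so part of the Ighj2 difference lies in sequences with unclear tags. Between the polymerase libraries, Ighj2 made up 30.3% of Q5_Q5 and 32.5% of Q5_vent, a difference of -2.14 points (interval -3.13 to -1.15), and Ighj4 27.5% and 26.2%, a difference of 1.27 points (interval 0.328 to 2.21). Ighj1 (18.3% and 17.9%) and Ighj3 (23.9% and 23.5%) had intervals including 0. Without sequences whose primer tag is marked unclear, which were 8.21% of Q5_Q5 and 12.9% of Q5_vent, the Ighj2 difference was -0.283 points (interval -1.27 to 0.707), the Ighj3 difference was 0.956 points (interval -0.00124 to 1.91) and the Ighj4 difference was -0.160 points (interval -1.19 to 0.866). Of the sequences removed, 76.2% in Q5_Q5 and 72.5% in Q5_vent were called Ighj2, so the removal itself lowers the Ighj2 share, unequally in the 2 libraries.

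For D families, all intervals of the differences over sequences included 0. DSP2 made up 42.3% at 5 µg and 42.0% at 500 ng, DFL16 39.7% and 40.3%, DQ52 5.99% and 5.99%, and DST4 5.82% and 5.65%. In Q5_Q5 and Q5_vent the shares were 42.3% and 43.0% for DSP2, 39.7% and 39.5% for DFL16, 6.23% and 6.28% for DQ52, and 5.78% and 5.44% for DST4. With 1 count per deposited clonotype, which joins different CDR3s, the difference between 5 µg and 500 ng was 4.92 points for DFL16 (interval 3.60 to 6.24), -1.35 for DQ52 (interval -1.88 to -0.814) and -0.851 for DST4 (interval -1.41 to -0.292), and between the polymerase libraries 0.715 for DST4 (interval 0.167 to 1.26). Depth was not made equal for these clonotype counts and cannot be told apart from input or polymerase. No sequence lacked a V call, so incomplete D to J joins were not counted: 0 of 228609 sequences.

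Productive rearrangements, in frame and without a stop codon, made up 73.3% of sequences at 5 µg (Wilson interval 73.0 to 73.5) and 72.7% at 500 ng (71.8 to 73.7). They made up 73.0% at 1 µg and 73.4% at 2.5 µg. The share was 73.9% in Q5_Q5 (73.2 to 74.6) and 72.6% in Q5_vent (72.0 to 73.3), a difference of 1.30 percentage points (interval 0.358 to 2.24). Productive CDR3s were on average 37.9 bases long at 5 µg and at 500 ng (SD over sequences 6.83 and 6.85), and 38.0 and 37.9 bases in Q5_Q5 and Q5_vent (SD 6.85 and 6.81). The differences were 0.0171 bases (interval -0.158 to 0.192) and 0.114 bases (interval -0.0559 to 0.284). With 1 count per deposited clonotype, 5 µg and 500 ng differed by -5.63 points in the productive share (interval -6.90 to -4.36) and by 2.74 bases in CDR3 length (interval 2.51 to 2.97). These clonotypes were counted without thinning to equal depth, and they join different CDR3s. An effect of input therefore cannot be told apart from depth and clonotype grouping in these 2 differences.

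Clones were nearly all small. Defined by V gene, J gene and CDR3, 98.8% to 99.7% of clones were seen a single time, and the largest clone held 0.0899% of the 5 µg sequences and 0.0919% of the 500 ng sequences. The 10 largest clones held 0.410% and 0.471%. At 8704 sequences per library, the deposited clonotypes numbered 6183 at 5 µg (SD 39.7 over 100 draws), 6154 at 500 ng, 6100 in Q5_Q5 (SD 30.9) and 6172 in Q5_vent (SD 33.7). Shannon diversity of deposited clonotypes at that depth was 12.3 bits at 5 µg and 12.2 bits in Q5_Q5.

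Some clones recurred across libraries. The 5 µg and 500 ng libraries shared 157 clones of the same V gene, J gene and CDR3, which is 1.82% of the smaller library's clones, and Q5_Q5 and Q5_vent shared 80 (0.535%). After thinning each library to 8704 sequences these numbers were 30 and 27. Of all clones, 221096 were in a single library, 1741 in 2 or more and 15 in all 6. The most abundant of the 15 was an out-of-frame Ighv2-6 to Ighj1 join with the CDR3 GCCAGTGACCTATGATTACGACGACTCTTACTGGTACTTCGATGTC, seen 217 times, at 0.0899% to 0.126% per library. Next were a productive Ighv1-36 to Ighj4 join with the CDR3 amino acids ATIYYDYDAYAMDY, seen 188 times at 0.0732% to 0.0997%, an Ighv12-3 to Ighj4 join (AGDTTGYYAMDY, 104 times) and an Ighv11-2 to Ighj1 join (MRYSNYWYFDV, 92 times). Ighv11-2 and Ighv12-3 made up 4.60% of shared clones (80 clones, interval 3.71 to 5.68) and 1.00% of clones seen in a single library (interval 0.962 to 1.05). Ighv5-2 made up 5.00% (interval 4.07 to 6.12) and 1.67% (interval 1.62 to 1.73), and productive joins 69.3% (interval 67.1 to 71.4) and 73.4% (interval 73.2 to 73.6). Joins without any base between the aligned V, D and J segments made up 6.03% of shared clones (interval 5.01 to 7.25) and 1.09% of the others (interval 1.05 to 1.14). The deposited lengths count untemplated N bases of terminal transferase and palindromic P bases together.

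Mismatches to the germline V gene, which polymerase errors and somatic mutation both leave, were less frequent in Q5_Q5 than in Q5_vent. At least 1 mismatch was found in 4.50% of Q5_Q5 sequences (interval 4.18 to 4.84) and 7.76% of Q5_vent sequences (interval 7.39 to 8.14), a ratio of 0.580 (interval 0.531 to 0.633). The gap lay in sequences with 1 or 2 mismatches, 2.81% of Q5_Q5 and 6.12% of Q5_vent (ratio 0.460, interval 0.413 to 0.513). Sequences with 5 or more made up 1.17% and 1.13% (ratio 1.03, interval 0.848 to 1.26), and over the 6 libraries they were 0.161% to 0.261% of productive and 3.45% to 4.51% of non-productive sequences. Among sequences with 1 or 2 mismatches, 8 of the 12 kinds of base change had an interval of the ratio below 1 and 4 an interval including 1. G-to-T changes had a ratio of 0.149 (interval 0.0872 to 0.254), C-to-A changes 0.167 (interval 0.0891 to 0.313) and G-to-A changes 0.320 (interval 0.239 to 0.427), per aligned V base and written as germline base to sequenced base. The 4 were A-to-C with a ratio of 1.01 (interval 0.745 to 1.36), C-to-G with 1.21 (interval 0.735 to 1.99), A-to-G with 0.813 (interval 0.643 to 1.03) and T-to-G with 0.547 (interval 0.293 to 1.02). In the input series at least 1 mismatch was found in 9.23% of sequences at 500 ng, 8.35% at 1 µg, 8.53% at 2.5 µg and 8.06% at 5 µg, a ratio of 0.873 between 5 µg and 500 ng (interval 0.815 to 0.935). Sequences with 3 or 4 mismatches made up 0.440% at 5 µg and 0.666% at 500 ng (ratio 0.660, interval 0.503 to 0.866).

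**Figure D3:**
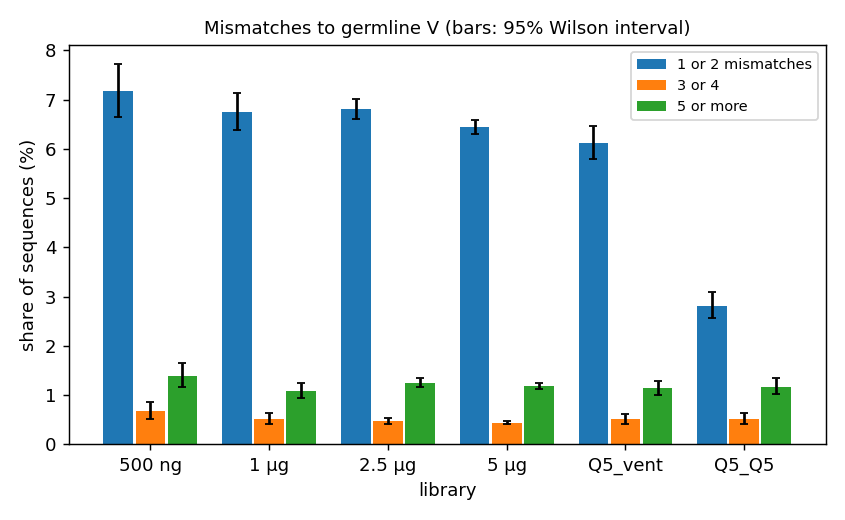
Share of sequences in percent (vertical axis) with 1 or 2, 3 or 4, and 5 or more mismatches to the germline V gene in each of the 6 libraries (horizontal axis), with 95% Wilson intervals for counting error. The share with 1 or 2 mismatches is 2.81% in Q5_Q5 and 6.12% in Q5_vent, while the share with 5 or more is 1.17% and 1.13%.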

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

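All tests in this part were chosen after the results were seen. Primer tags, which no comparison used to assign genes, disagreed with the called J gene in part of the sequences whose tag is marked unclear. The share naming another J gene than the call was 23.2% at 500 ng, 23.5% at 1 µg, 20.4% at 2.5 µg, 21.3% at 5 µg, 4.20% in Q5_vent and 2.51% in Q5_Q5. Among tags not marked unclear it was at most 0.0267%. Of sequences with an unclear tag, 62.6% to 76.2% were called Ighj2 over the 6 libraries.

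The lower share of sequences with 1 or 2 V mismatches in Q5_Q5 was set against several explanations. More reads per sequence do not account for it, since the ratio to Q5_vent was 0.493 (interval 0.425 to 0.571) at equal read support, nor do near-identical V genes or short alignments, with a ratio of 0.310 (interval 0.264 to 0.365) among long single-gene alignments. Fewer somatically mutated cells as the whole cause would lower heavily mismatched productive sequences as well. Their ratio (3 or more mismatches, 63 sequences in Q5_Q5 and 83 in Q5_vent) was 0.967 (interval 0.697 to 1.34), above the interval for 1 or 2 mismatches over all sequences. Without 22 V genes in which over 5% of 5 µg sequences had 3 or more mismatches it was 0.857 (interval 0.583 to 1.26), against 0.456 (interval 0.408 to 0.509) for 1 or 2 over all sequences. Sequences with 5 or more mismatches were 0.252% of productive and 3.78% of non-productive sequences in Q5_Q5. Heavy mismatch is thus not shown to track somatic mutation, and this comparison cannot decide on that explanation. The polymerase pair and any other difference between these libraries cannot be told apart, because the ratio of 0.460 rests on 1 library per pair.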

How the results depend on the processing

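Chosen after the data were seen were 1 count per clone of V gene, J gene and CDR3, the removal of unclear primer tags, and the mismatch class, read support and alignment length settings. Of 565 alternative values for 104 results, 216 concern single V genes: 21 kept an interval excluding no difference, 27 lost it, 7 gained it and 161 had it in neither. The sign changed in 31, of which 2 had such an interval as reported (Ighv1-4 at 0.0207 with single-gene V calls, Ighv3-2 at 0.12 for 5 µg against 1 µg). Of 180 for V families, 5 kept such an interval, 11 gained it and 164 had it in neither, and the sign changed in 36, all without it as reported. The ratios of recovered sequences, recovered clones and mismatch shares kept their side of 1 under every alternative run of each. No paired analysis was possible because, in the comparisons between groups, each group has 1 library, and for the same reason none could be left out of a group. No trend over the 4 DNA amounts was fitted. Productive and out-of-frame shares were set against each other within libraries: leaving out each library in turn, an added alternative, gave mean log2 ratios of -5.97 to -5.83 for Ighv5-2, and the mean kept its sign for all 79 genes. A filter for more than 1 read was not run, since every sequence has at least 3. Unless stated, the cause was not tested.

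With 1 count per deposited clonotype, which joins different CDR3s, differences between 5 µg and 500 ng in points were -5.63 for the productive share, 4.92 for DFL16, -1.35 for DQ52, -0.851 for DST4, -0.740 for D-proximal, 2.35 for middle and -1.61 for distal families, with intervals excluding 0 except for D-proximal families. This setting did not thin the libraries to equal depth, so its values mix input with depth and clonotype grouping. CDR3 length differed by 2.74 bases, 4 V genes stood apart, 13 had an interval excluding 1, and r was 0.977. For the polymerases DST4 differed by 0.715 points and CDR3 length by -0.145 bases, and r was 0.992. V genes standing apart between 5 µg and 500 ng (1 as reported) were 2 at a minimum of 30 sequences and 0 at a minimum of 300, at 2-fold, with widened intervals, after thinning, among productive sequences and for 5 µg against 1 µg. Those with an interval excluding 1 (4) were 1 among productive sequences, 0 with widened intervals, 2 after thinning and 10 for 2.5 µg against 500 ng. For the polymerases (3) they were 1 among productive sequences and 0 with widened intervals. On log2 shares r was 0.985 and 0.987.

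Without unclear primer tags the polymerase difference was -0.513 points for Ighj1, -0.283 for Ighj2, 0.956 for Ighj3 and -0.160 for Ighj4. Among productive sequences it was 1.06 points for Ighj3 and 0.401 for Ighj4. The CDR3 difference over all sequences was 0.197 bases, and the ratio of distinct clones at equal depth was 0.987 for deposited clonotypes and 1.00 (1.0027, above 1) by V gene, J gene and CDR3. Shared clones by CDR3 alone were 299 between 5 µg and 500 ng and 127 between the polymerases. Shared clones by V gene, J gene and CDR3 after thinning were 30, 27 and, in all 6 libraries, 9, from fewer sequences. Depth limits genes with under 100 sequences.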

Other observations

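Of the tests in this part, all but that on neighbouring identifiers were chosen after the result was seen, and so were the genes named apart from Ighv11-2 and Ighv12-3. V gene shares differed between productive and out-of-frame rearrangements. Out-of-frame joins are not under selection for their protein. In the 5 µg library, 83 genes had at least 300 productive and out-of-frame sequences together. Of these, 79 had an interval excluding no difference, 50 higher and 29 lower among productive sequences, against 4.15 expected by counting error. The sign was the same in all 6 libraries for 74 of the 79. This minimum left out Ighv1-70 and the annotated pseudogenes Ighv4-2 and Ighv3-2, with 326, 382 and 344 sequences in all. The annotated pseudogenes Ighv7-1 and Ighv7-3 were kept, at log2 ratios of -2.13 and 0.505. Ighv5-2 (chromosome 12, 113578504 to 113578990), among the V genes nearest to the D genes, made up 0.121% of productive and 6.38% of out-of-frame sequences, a log2 ratio of -5.71 at 5 µg and -5.90 ± 0.26 (SD, n = 6 libraries). The libraries may share an animal, so this SD and the count of like signs describe libraries and not animals. Ighv1-11 had -5.31 and Ighv3-3 -4.30 at 5 µg. Ighv1-80 had 2.00, Ighv14-2 1.68 and Ighv1-82 1.66. With 1 count per clone of V gene, J gene and CDR3, 77 of the 79 kept their sign and an interval excluding 0.

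The D-proximal families Ighv2 and Ighv5 held 10.4% to 10.8% of productive and 23.8% to 25.2% of out-of-frame sequences. The distal families went opposite ways: Ighv1 held 61.5% to 62.7% of productive and 39.3% to 41.3% of out-of-frame sequences, Ighv8 4.74% to 5.41% and 5.88% to 6.70%, where the interval of the ratio reached up to 1.04. The families between held 22.0% to 22.7% and 27.8% to 28.9%, and they too went opposite ways. The ratio of productive to out-of-frame shares was 1.89 to 2.65 for Ighv14 and 1.71 to 2.09 for Ighv9, and 0.0718 to 0.199 for Ighv11, 0.0936 to 0.185 for Ighv12, 0.190 to 0.277 for Ighv13, 0.137 to 0.224 for Ighv15, 0.195 to 0.337 for Ighv4 and 0.675 to 0.794 for Ighv3, with intervals excluding 1 in all 6 libraries. For Ighv6, Ighv7 and Ighv10 an interval included 1 in at least 1 library. Members of a family did not all go the same way. At 5 µg the log2 ratio was 1.01 for Ighv3-6 and -4.30 for Ighv3-3, and 0.993 for Ighv5-17 and -5.71 for Ighv5-2. Family shares also include genes annotated as pseudogenes, such as Ighv4-2 and Ighv3-2. The B-1 genes Ighv12-3 and Ighv11-2 had log2 ratios of -3.04 and -2.26 by sequences and -3.99 and -3.52 by clones. Ighv2-6 had -3.77 by sequences and -3.30 by clones, as a single clone made up 29.4% of its out-of-frame sequences.

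Deposited clonotypes were 70.7% of the sequence number at 500 ng and 42.5% at 5 µg. In a set of 100 draws at equal depth, separate from that behind the mean numbers of clonotypes, the ratio of distinct clonotypes averaged 1.00 (1.00324), so the number of sequences per library may account for the gap. Clonotypes also join different CDR3s: of sequence pairs drawn within a clonotype at 5 µg, 4.07% (interval 3.71 to 4.47) had the same CDR3, and the median pair differed at 31.7% of CDR3 bases and 8% of bases of the shorter deposited junction. A candidate explanation is that clonotypes were grouped on that junction. No biological explanation was tested.

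The out-of-frame Ighv2-6 clone and the productive Ighv1-36 clone recurred in all 6 libraries at like shares. Reads carried over between libraries are argued against by 0 combinations of clone and identifier in more than 1 library. A neighbouring identifier within 1 base was found for 0.494% (interval 0.136 to 1.78) of the sequences of these clones. This value cannot decide on copies of few molecules with identifier errors. The sequences were deduplicated before deposit, and identifiers that close may have been merged then. Some repeated copies stay open. The number of distinct V alignment lengths was below the mean of random sets of sequences in 10 of 12 combinations of clone and library. It was lower by over 2 SD in 3, Ighv2-6 at 1 µg (12 among 17, against 15.2, SD 1.32) and Ighv1-36 in Q5_vent (12 among 17, against 15.2, SD 1.44) and Q5_Q5 (8 among 11, against 10.2, SD 0.912). The random sets gave the same mean for both clones at 1 µg, and so were not matched to V gene. Sequences of a clone share a V gene and CDR3, so fewer distinct lengths can arise without copies, and this comparison cannot decide. As a hypothesis, the 2 alleles of 1 expanded clone and separate clones of like size cannot be told apart: the Ighv1-36 join made up 46.4% of their sequences (interval 41.6 to 51.3), but the pair was picked after its like counts were seen, and 10 of 53 other pairs of a productive and a non-productive clone also had every interval including 50%. No other biological explanation was tested, and the labels do not say whether libraries share an animal. Of non-productive joins found in all 6 libraries, that of Ighv2-6 had 1 and 6 bases between aligned V, D and J segments. Those of Ighv2-4 had 3 and 4, Ighv13-2 7 and 2, and Ighv6-3 1 and 2, while Ighv2-6-1 and Ighv10-1 had 0. The joins with such bases argue against 6 libraries without any animal or DNA in common.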
